A study of Mus musculus with 6 samples.

How the data were processed

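RNA sequencing libraries of primary mouse neural stem cells from the adult subventricular zone were compared in 2 groups of 3: cells infected with a GFP vector (Control) and cells infected with a DEK and GFP vector (DEK cOE). Groups and replicate numbers were taken from the sample titles. Per the submitters' processing notes, reads were aligned with HISAT2 version 2.0.5 and the genome build is mm39. The counting tool, the annotation release, the strand setting and the library kit's strandedness are not given in the sources used here, so overlapping and antisense genes could not be told apart.

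The deposited tables hold FPKM-type values made by the authors, per kilobase of gene length and scaled for depth, for 55802 features in each of 6 libraries. The file headers name no unit. The unit was read from the values: each value times the deposited gene length was a whole multiple of 1 step per library for 100% of values above 0, within a tolerance of 0.05 reads. The reads behind the values could therefore be recovered. Their sum was between 0.945 and 1.09 times the depth denominator that the step implies, so the authors' denominator is not the plain sum of the reads in the table, and how it was made is not given in the sources used here. Recovered reads numbered between 13268958 and 16852489 per library. Per-sample columns not used numbered 0. Floors that follow from a count of reads cover counting error only.

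The design written before the data were examined had 1 plan for counts and 1 for normalized values, and the plan for normalized values was used. Features with at least 1 FPKM in at least 3 libraries were kept, which left 13128, of which 138 carry no gene name. Values were transformed to log2(FPKM + 1) with the authors' scaling, and DEK cOE was compared with Control with limma 3.58.1 in R 4.3.3 (linear model on group, empirical Bayes with a mean-variance trend), two-sided, with Benjamini-Hochberg adjustment over all tested features. A feature was called at an adjusted p below 0.05. No replicate block was used in the comparison, because the labels do not say that equal numbers share an animal, culture or day. Values are given as mean ± SD in FPKM over 3 libraries.

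Gene lists were written before the data were examined. There were 31, and the 27 with at least 5 tested genes were tested with camera (limma) at its preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation 0 lists were called, against 15 with the preset one. The smallest adjusted p was then 0.071. For the quiescence, oligodendrocyte and G1/S lists the estimated correlation was -0.010, -0.064 and 0.0059, below the preset value. For these lists, correlation between genes was therefore not what removed the call. With an estimated correlation, camera also takes its degrees of freedom from the few libraries and not from the many genes, which by itself raises p. Counts of called members are over all tested genes, and counts adjusted over the list alone stand beside them. The lists cover quiescent and activated neural stem cells, G1/S, G2/M, p53 targets, neurons, oligodendrocytes, reactive astrocytes, other cell types of the brain, interferon and NF-kappaB responses, Notch, BMP and TGF-beta, Wnt, chromatin partners of DEK, lysosome, lipid and energy metabolism, immediate-early genes, stress responses, growth factors, ribosomal, mitochondrial and sex-linked genes.

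The genes named in the text follow a rule written before the data were examined: Dek, then the 12 largest rises and 12 largest falls among called genes with a curated symbol, a mean of at least 1 FPKM and no overlap between groups (which chance gives for 10% of genes with 3 against 3 libraries), then up to 4 called members of each list by smallest p, or the 2 most abundant members where none is called. Some genes that the rule selects are not reported here. Genes outside the rule are said to have been singled out afterwards.

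The comparison was tested on simulated data with the real means and the spread between libraries of each gene. With the spread of all 6 libraries, 0%, 18%, 62% and 92% of genes changed 1.5-, 2-, 4- and 8-fold were called, with 3 false calls among 12928 unchanged genes. With the spread without Control 3, the shares were 20%, 68%, 92% and 96%, with 8 false calls. At each fold 50 genes were changed, far fewer than the 1725 features called in the data. The Benjamini-Hochberg adjustment was therefore stricter in the simulation, and these shares can understate the sensitivity of the real comparison. Of 200 random gene sets, 4 had a camera p below 0.05 in simulated data. Each gene was drawn independently, so neither the false calls nor the random sets show the error rate among correlated genes.

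Libraries were compared in pairs before averaging. The chi-square per degree of freedom of recovered reads was between 7.46 and 126 within groups, so no pair of libraries differed by as little as sampling noise, and each counted as 1 replicate. GC content came from the longest transcript of each gene in the GENCODE M21 annotation and was available for 98.1% of tested features. No coordinates of that annotation, which is on another genome build than the files, were used. Coordinates are those of the deposited tables.

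Alternatives planned before the data were examined were a pseudocount of 0.1, no filter on low values, a filter of at least 1 RPM of recovered reads in 3 libraries, quantile normalization, median-ratio, upper-quartile and plain library size scaling of the recovered reads, a replicate block, each library left out in turn, an adjusted p below 0.01 and a log2 fold change of at least 1. Alternatives that need a table of counts were planned for such a table and not run, since the values are FPKM. Alternatives added after seeing the data were the removal of each library's GC trend (loess, span 0.3), sample weights, voom on the recovered reads, a term for libraries whose deviation rises or falls with GC content, and the removal of Control 3 and the GC trend together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.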

Results

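Gene expression was measured by RNA sequencing in primary neural stem cells from the subventricular zone, a neurogenic niche of the adult mouse brain. The cultures were infected with an adeno-associated virus (AAV9) that carried either GFP alone or DEK and GFP under the promoter of Gfap, a gene of astrocytes and neural stem cells. DEK is a chromatin-bound protein with histone chaperone activity. The GFP group is called Control and the DEK group DEK cOE, with 3 libraries each, and the labels name 24 hours without saying whether this is the time since infection or the age of the cultures. The labels do not say whether replicates came from separate animals or cultures, so p-values measure only the spread between these libraries. The series title links DEK to the exit of neural stem cells from quiescence, and the comparison of DEK cOE with Control addresses which transcripts differ once DEK is overexpressed.

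The reads behind the deposited values numbered 15944587, 16316563 and 14849318 in Control 1, 2 and 3, and 16852489, 13268958 and 13665481 in DEK cOE 1, 2 and 3. In a transcript of 1 kilobase, 1 read corresponded to between 0.0582 and 0.0751 FPKM, so genes near 1 FPKM rested on few reads. Control 3 stood apart from the other libraries. Its Pearson correlation across genes was 0.884 with both Control 1 and Control 2, against 0.985 between those libraries and 0.972 to 0.983 within DEK cOE. Across groups, DEK cOE 1 correlated with Control 1 and 2 at 0.926. Control 3 correlated with DEK cOE 1, 2 and 3 at 0.880, 0.896 and 0.885, about as closely as with its own group. Mitochondrial transcripts took 6.58% of its reads, against 4.02% to 4.92% elsewhere. Its deviation from the mean of all libraries fell with the GC content of the transcript (Spearman's rho across genes = -0.565), whereas that of Control 1 and Control 2 rose (0.559 and 0.537). Genes are not independent replicates, so these correlations describe libraries.

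**Figure D1:**
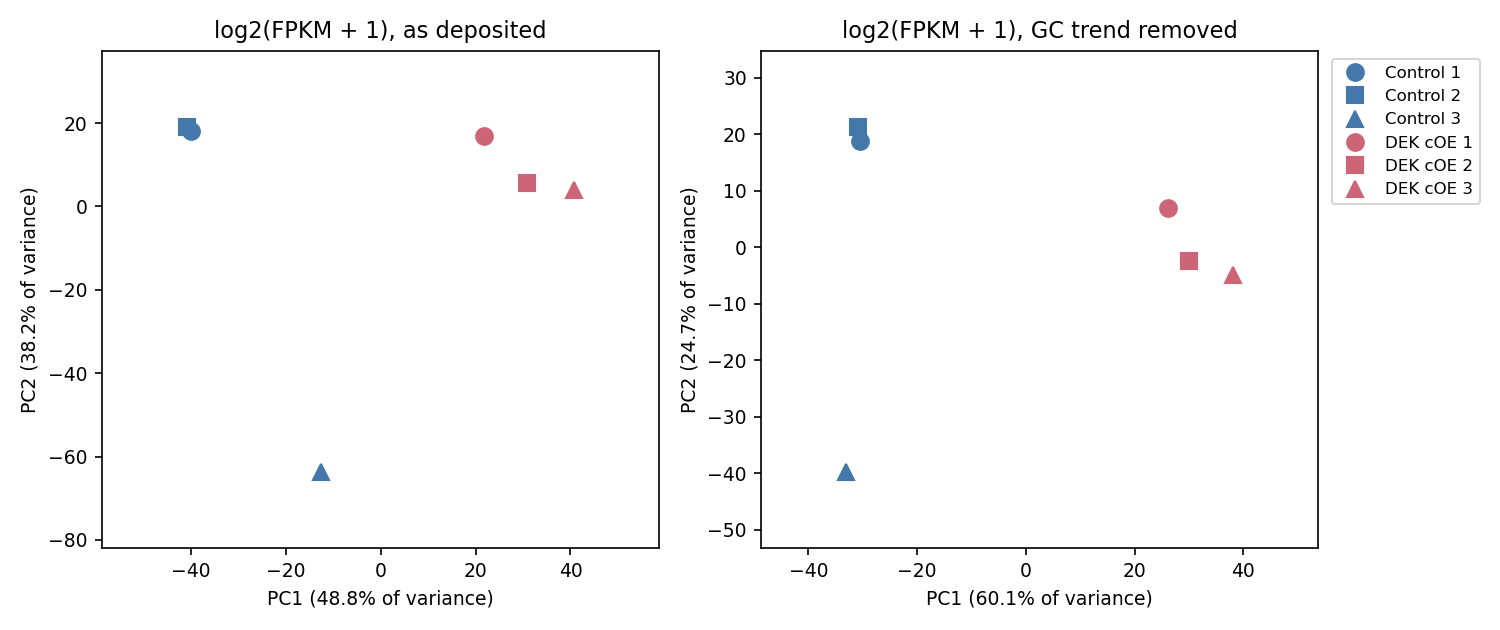
Principal components of log2(FPKM + 1) for the 6 libraries, as deposited (left) and with each library's GC trend removed (right); colour gives the group and the marker shape the replicate number. PC1 separates DEK cOE from Control and PC2 separates Control 3 from the other libraries, with 38.2% of the variance on PC2 as deposited and 24.7% after the GC trend was removed.

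Dek (ENSMUSG00000021377, chromosome 13, 47238251 to 47259677 on the minus strand, mm39) was 19.7 times as abundant in DEK cOE as in Control. Its level was 16.3, 17.1 and 24.0 FPKM in Control 1, 2 and 3 and 338, 353 and 437 FPKM in DEK cOE 1, 2 and 3, or 19.1 ± 4.22 against 376 ± 53.4 FPKM (SD, n = 3 per group). The log2 fold change was 4.24 with a standard error of 0.20 (limma, adjusted p = 4.5e-04), and all 3 DEK cOE libraries lay above all 3 Control libraries. The labels do not give the sequence of the transgene, and reads from the vector and from the endogenous gene were not told apart.

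Hmga2, a chromatin protein of fetal and young neural stem cells, rose from 0.539 ± 0.0723 to 16.8 ± 2.77 FPKM, and its relative Hmga1 rose from 12.6 ± 7.05 to 77.2 ± 17.0 FPKM. Nptx1, a secreted neuronal pentraxin, rose from 6.24 ± 2.26 to 115 ± 1.41 FPKM. Smoc1, which encodes a secreted calcium-binding matrix protein, fell from 129 ± 7.80 to 8.78 ± 1.27 FPKM, and Lrrn1, a leucine-rich repeat membrane protein, from 130 ± 20.3 to 9.37 ± 0.757 FPKM (SD, n = 3 per group). Over 13128 tested features, 804 were higher and 921 lower in DEK cOE (limma, Benjamini-Hochberg adjusted p below 0.05), and 309 and 461 of these had a log2 fold change of at least 1 in size.

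On the log2(FPKM + 1) scale, the 12 largest rises, Dek included, had log2 fold changes from 2.57 to 4.24. After Dek, Nptx1 (4.06) and Hmga2 (3.52) came Clcf1, a cytokine of the CNTF family (3.27), and Syt4, a vesicle protein (3.19). Rflna (2.82), Hopx (2.80), the secreted neuropeptide precursor Vgf (2.76), the kinase gene Sgk1 (2.75), Hmga1 (2.69), the interferon-induced Ifit1 (2.61) and the membrane protein gene Tmem158 (2.57) followed. The 12 largest falls on this scale ran from Smoc1 (-3.74) and Lrrn1 (-3.65) to Apoe, the main apolipoprotein of glia (-2.54). Between these lay Gjc3, a gap junction gene of oligodendrocytes (-3.42), the nicotinic receptor gene Chrna4 (-3.25), Als2cl (-3.04), the oligodendrocyte-myelin glycoprotein gene Omg (-2.90) and the Notch ligand gene Dll1 (-2.90). Spon1 (-2.79), Aif1l (-2.75), the calcium sensor gene Ncald (-2.71) and Asrgl1 (-2.57) completed them. The order differs by ratio of group means, where Oasl1 (39.9 times as high in DEK cOE), Hmga2 (31.2 times) and Hopx (19.9 times) lie above Dek (19.7 times), and Gjc3 (40.0 times as high in Control), Meig1 (22.1 times) and Als2cl (19.6 times) above Smoc1 (14.7 times). Such ratios are imprecise where 1 group is near 0. Meig1 was at 0.106, 0 and 0.199 FPKM in DEK cOE 1, 2 and 3, and Oasl1 at 0.0905 ± 0.0219 FPKM in Control. Of the 24 largest rises and falls on the log2(FPKM + 1) scale, 22 were called in all 6 fits that left out 1 library. The 24 had been selected for large fold changes among called genes without overlap between groups. The fits reuse the same libraries, so this share is not independent support. Hmga1 was called in 3 of these fits, those without a Control library, with a highest adjusted p of 0.063 without DEK cOE 3. Apoe was called in 1, the fit without Control 3, with a highest adjusted p of 0.090 without DEK cOE 3, and Control 3 held 306 FPKM of Apoe against 987 and 1132 FPKM in Control 1 and 2.

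**Figure D2:**
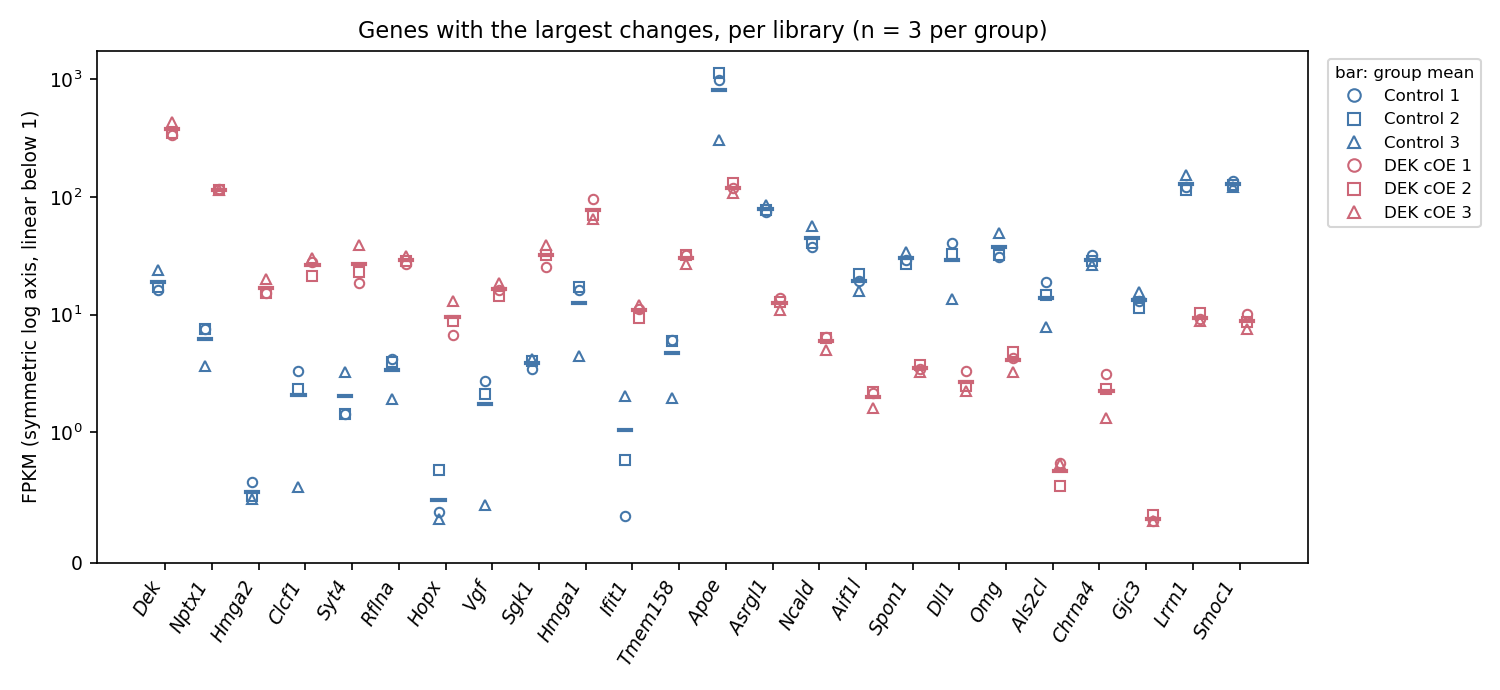
FPKM (symmetric log axis, linear below 1) of the 12 genes with the largest rise and the 12 with the largest fall, with 1 point per library and a bar at the mean of each group. DEK cOE libraries lie above all Control libraries for the 12 genes on the left (Dek 376 against 19.1 FPKM) and below them for the 12 on the right (Smoc1 8.78 against 129 FPKM). The selection of these genes required this separation.

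The count of called genes changed with the library left out. It was 1725 with all 6 libraries and 5901 without Control 3 (3142 higher, 2759 lower), with all 1725 called again in the same direction. It was 693 without Control 1, 761 without Control 2, 743 without DEK cOE 1, 419 without DEK cOE 2 and 394 without DEK cOE 3. Each such fit has 1 library fewer, so lower power alone can reduce the count. In these fits log2 fold changes correlated across genes with those of all 6 libraries at 0.968 to 0.989, against 0.917 without Control 3. Every shared call kept its sign. Counts without Control 3 given for the gene lists below are to be read against the 3142 higher and 2759 lower of all 13128 features in that fit.

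Of 33 tested genes associated with quiescent neural stem cells, 15 fell and 2 rose (20 and 3 adjusted over the list alone, 22 and 5 without Control 3). The list was lower than other genes in camera (adjusted p = 9.1e-08, adjusted p = 0.071 with an estimated correlation). Ndrg2, a growth-restraining gene of astrocytes, fell from 132 ± 11.1 to 22.8 ± 3.24 FPKM, and the glutamine synthetase gene Glul from 109.9 ± 4.6 to 25.3 ± 4.14 FPKM. Hopx, a marker of some quiescent stem cell pools, was among the 2 that rose, from 0.478 ± 0.199 to 9.52 ± 3.14 FPKM. These 3 genes were called in all 6 fits that left out 1 library. Gfap, whose promoter drives the vectors, was 84.2 ± 14.7 FPKM in Control and 52.97 ± 1.23 FPKM in DEK cOE, a difference that missed the threshold (adjusted p = 0.056) and passed it without Control 3 (adjusted p = 0.0022).

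Of 36 tested genes of G2/M and mitosis, 23 rose and 0 fell (35 and 0 adjusted over the list alone, 35 and 0 without Control 3). The list was called (camera, adjusted p = 4.7e-14), with adjusted p = 0.20 with an estimated correlation. The ubiquitin-conjugating enzyme gene Ube2c rose from 4.96 ± 1.30 to 15.5 ± 2.60 FPKM, the cytokinesis gene Ect2 from 2.36 ± 0.675 to 6.09 ± 0.727 FPKM, the kinetochore gene Ndc80 from 0.712 ± 0.137 to 2.03 ± 0.194 FPKM and the cyclin gene Ccna2 from 3.58 ± 0.803 to 7.40 ± 0.116 FPKM. Of 31 tested genes of G1/S and DNA replication, 8 rose and 0 fell (10 and 0 adjusted over the list alone, 15 and 0 without Control 3). Camera gave adjusted p = 2.4e-04 for this list, and adjusted p = 0.16 with an estimated correlation. Among the rises were the licensing factor gene Cdt1 (log2 fold change 0.97), Orc6 (0.75), the histone mRNA-binding gene Slbp (0.67) and the ribonucleotide reductase gene Rrm2 (0.60). Ube2c was called in 4 of the 6 fits that left out 1 library, and Ect2, Ndc80 and Cdt1 in 2. Ccna2, Orc6, Slbp and Rrm2 were called only without Control 3, with adjusted p-values of up to 0.14 otherwise.

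The 22 tested genes of activated neural stem cells and transit-amplifying progenitors went both ways, with 5 higher and 6 lower (5 and 9 adjusted over the list alone, 8 and 10 without Control 3), and the list was not called (camera, adjusted p = 0.35). The D-type cyclin genes Ccnd1 (76.5 ± 9.98 to 236 ± 35.0 FPKM) and Ccnd2 (55.0 ± 8.67 to 175 ± 14.7 FPKM) rose. Sox4 fell from 204 ± 25.9 to 51.5 ± 2.44 FPKM and Dll1 from 28.9 ± 13.9 to 2.68 ± 0.580 FPKM. Egfr, the receptor of the mitogen EGF, fell from 76.4 ± 26.5 to 16.5 ± 2.44 FPKM (log2 fold change -2.11, adjusted p = 0.0050). Egfr and Gfap were singled out after their values were seen. Among 27 tested p53 targets and inhibitors of cyclin-dependent kinases, Plk2 (0.70), Tnfrsf10b (0.76) and Cdkn2b (0.65) rose and Sesn1 (-0.98) fell, and the list was not called (3 and 1 adjusted over the list alone, 11 and 5 without Control 3, adjusted p = 0.18). Sesn1 was called in 4 of the 6 fits that left out 1 library, and Plk2, Tnfrsf10b and Cdkn2b only without Control 3 (adjusted p of up to 0.18 otherwise).

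Of 17 tested neuroblast and neuron genes, Dlx2 (log2 fold change 1.04), Nefl (1.21) and Snap25 (0.66) rose, and Gad1 (-0.72) and Stmn1 (-1.07) fell (4 and 2 adjusted over the list alone, 5 and 3 without Control 3). Camera placed the list up at adjusted p = 0.98, with a median of -0.09 and a mean of 0.03. Stmn1 was singled out after its values were seen. Dlx2 was called in all 6 fits that left out 1 library, Nefl in 2, and Gad1 and Snap25 only without Control 3 (adjusted p of up to 0.14 otherwise). Of 9 tested oligodendrocyte-lineage genes, 3 fell and 0 rose (4 and 0 adjusted over the list alone, 6 and 0 without Control 3): Bcas1 from 4.18 ± 1.04 to 0.468 ± 0.221 FPKM, the myelin enzyme gene Cnp from 72.7 ± 22.6 to 23.9 ± 1.76 FPKM, and Mal from 1.16 ± 0.117 to 0.406 ± 0.153 FPKM. The list was lower (camera, adjusted p = 0.0027, adjusted p = 0.16 with an estimated correlation). Bcas1 was called in all 6 fits that left out 1 library, Cnp in 2 and Mal in 1.

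Of 20 tested genes of the type I interferon response, 7 rose and 0 fell (8 and 0 adjusted over the list alone, 9 and 0 without Control 3). They included Ifit1 (1.05 ± 0.858 to 10.9 ± 1.29 FPKM), the RNA sensor gene Ifih1 (0.819 ± 0.0848 to 3.51 ± 0.450 FPKM), the antiviral gene Rsad2 (0.992 ± 0.559 to 5.82 ± 1.13 FPKM) and Oasl1 (0.0905 ± 0.0219 to 3.61 ± 0.721 FPKM). Of 12 tested NF-kappaB and cytokine genes, 5 rose and 0 fell (6 and 0 adjusted over the list alone). Examples are the chemokine gene Ccl2 (1.02 ± 0.0288 to 4.64 ± 1.37 FPKM) and the macrophage growth factor genes Csf1 (10.5 ± 2.78 to 22.1 ± 0.826 FPKM) and Il34 (0.498 ± 0.110 to 1.57 ± 0.106 FPKM). Both lists were called (camera, adjusted p = 7.8e-04 and 5.4e-04), with adjusted p = 0.29 and adjusted p = 0.31 with an estimated correlation. Of 23 tested reactive-astrocyte genes, 9 rose and 3 fell (13 and 3 adjusted over the list alone, 14 and 6 without Control 3). The rises were led by Clcf1, the chemokine gene Cxcl10 (3.14 ± 0.15 to 22.6 ± 5.06 FPKM), Tm4sf1 and Emp1 (1.72 ± 0.383 to 5.71 ± 0.926 FPKM). This list was called (adjusted p = 0.013, adjusted p = 0.31 with an estimated correlation), but not without Control 3 (adjusted p = 0.072, in a range of 0.0065 to 0.072 with 1 library left out). Csf1, Il34 and Lif (log2 fold change 1.02) were called in 2, 1 and 1 of the 6 fits that left out 1 library.

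Of 25 tested BMP and TGF-beta genes, 10 rose and 0 fell (12 and 0 adjusted over the list alone, 17 and 1 without Control 3). They included the latent TGF-beta binding protein gene Ltbp1 (3.14 ± 0.897 to 12.1 ± 0.413 FPKM), the mediator Smad3 (15.1 ± 0.508 to 27.2 ± 1.73 FPKM) and the pathway inhibitors Bambi (0.818 ± 0.111 to 3.36 ± 0.403 FPKM) and Smad6 (log2 fold change 1.24). Camera gave adjusted p = 1.2e-04 for this list (adjusted p = 0.16 with an estimated correlation). Of 17 tested Wnt genes, 3 rose and 7 fell (3 and 9 adjusted over the list alone, 3 and 11 without Control 3). The receptor genes Fzd1 (9.38 ± 0.458 to 51.5 ± 3.32 FPKM) and Fzd7 (5.79 ± 0.365 to 17.2 ± 2.53 FPKM) rose, and the ligand genes Wnt5a (26.8 ± 1.34 to 8.80 ± 0.198 FPKM) and Wnt7a (8.97 ± 1.66 to 1.87 ± 0.526 FPKM) fell. The list was called as lower by camera (adjusted p = 0.020, adjusted p = 0.22 with an estimated correlation) but not by fry (adjusted p = 0.12). Among 15 tested growth factor genes, Hbegf, an EGF receptor ligand (6.47 ± 0.841 to 41.0 ± 6.38 FPKM), Pdgfa (6.20 ± 0.414 to 22.6 ± 2.42 FPKM) and Vegfc (log2 fold change 0.73) rose and the BDNF receptor gene Ntrk2 (70.5 ± 12.9 to 25.8 ± 1.30 FPKM) fell. In this list 5 genes rose and 1 fell (6 and 3 adjusted over the list alone, 7 and 5 without Control 3), and the list was not called by camera (adjusted p = 0.37) but was called as higher by fry (adjusted p = 0.018). In the Notch list of 17 tested genes, Jag1 rose (4.87 ± 1.33 to 20.3 ± 1.17 FPKM), Notch2 (-0.94) and Dtx4 (-0.69) fell, and the list was not called (1 and 2 adjusted over the list alone, 3 and 6 without Control 3, adjusted p = 0.76, median -0.05, mean 0.03, test down). Of 29 tested immediate-early genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone, 11 and 3 without Control 3). The ERK phosphatase genes Dusp6 (27.8 ± 3.01 to 103 ± 5.17 FPKM) and Dusp5 (4.11 ± 0.639 to 17.5 ± 3.59 FPKM), Arc (1.41 ± 0.440 to 6.81 ± 1.74 FPKM) and Fosl2 (log2 fold change 0.89) rose. The list was called by camera (adjusted p = 0.0042, adjusted p = 0.56 with an estimated correlation) but not by fry (adjusted p = 0.15), nor by camera without Control 3 (adjusted p = 0.18, in a range of 5.1e-04 to 0.18 with 1 library left out). Smad6 and Notch2 were called in 5 of the 6 fits that left out 1 library, Smad3 in 2. Vegfc, Dtx4 and Fosl2 were called only without Control 3 (adjusted p of up to 0.14 otherwise). The other genes named in this group were called in all 6.

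Of 21 tested fatty acid oxidation genes, 6 fell and 0 rose (11 and 0 adjusted over the list alone, 15 and 0 without Control 3). Camera gave adjusted p = 1.8e-05 for this list, and adjusted p = 0.16 with an estimated correlation. The falls were led by Ucp2 (5.25 ± 2.05 to 0.880 ± 0.131 FPKM), the pyruvate dehydrogenase kinase gene Pdk4 (9.73 ± 1.76 to 4.13 ± 0.547 FPKM), Hadha (50.2 ± 3.92 to 27.4 ± 1.77 FPKM) and Acadl (213 ± 18.6 to 126 ± 3.77 FPKM). Of 30 tested nuclear genes of oxidative phosphorylation, 3 fell and 0 rose (3 and 0 adjusted over the list alone, 13 and 0 without Control 3): Ndufa1 (-1.10), Ndufa2 (-1.32) and Cox4i1 (329.9 ± 50.7 to 164.1 ± 25.2 FPKM). This list was called by camera (adjusted p = 0.0011, adjusted p = 0.43 with an estimated correlation) but not by fry (adjusted p = 0.092). Of 28 tested lysosome and autophagy genes, 5 fell and 0 rose (10 and 1 adjusted over the list alone, 17 and 2 without Control 3), with camera adjusted p = 0.0011, and adjusted p = 0.22 with an estimated correlation. The falls included the cholesterol export genes Npc1 (-0.72) and Npc2 (-0.87), the hexosaminidase gene Hexa (-0.75) and the cathepsin gene Ctsz (-0.68). Of 13 mitochondrially encoded transcripts, 10 had a log2 fold change above 0 and 0 were called. The glycolysis and hypoxia list was split, with 5 of 23 tested genes higher, such as Pfkp (0.91) and Slc2a3 (0.87), and 4 lower, such as Adm (-1.83) and Mxi1 (-0.93), at adjusted p = 0.98 (5 and 5 adjusted over the list alone, 8 and 6 without Control 3, median -0.01, mean 0.0060, test down). Among 27 tested genes of cholesterol and fatty acid synthesis, 3 rose, Lss (0.56) and Elovl6 (0.71) among them, and Thrsp (-1.54) fell (7 and 2 adjusted over the list alone, 14 and 4 without Control 3). This list was not called (adjusted p = 0.099). Without Control 3 it had adjusted p = 0.018 at the preset correlation, in a range of 0.018 to 0.22 with 1 library left out, and adjusted p = 0.54 with an estimated correlation. Of the genes named in this group, Adm was called in all 6 fits that left out 1 library. Ucp2, Pdk4, Pfkp, Mxi1, Slc2a3 and Thrsp were called in 4, Hadha, Ndufa1 and Ndufa2 in 3, and Npc1 and Cox4i1 in 2. Acadl, Npc2, Hexa, Ctsz, Lss and Elovl6 were called only without Control 3 (adjusted p of up to 0.17 otherwise).

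Of 30 tested chromatin partners of DEK and histone chaperones, 4 rose and 0 fell (4 and 0 adjusted over the list alone, 13 and 2 without Control 3). The 4 were Hmga2, Hmga1, the chaperone gene Nap1l1 (35.6 ± 7.30 to 61.7 ± 3.12 FPKM) and Set (43.6 ± 7.41 to 70.8 ± 5.54 FPKM). The list was called (adjusted p = 0.022, adjusted p = 0.31 with an estimated correlation), but not without Control 1 (adjusted p = 0.078, in a range of 0.0045 to 0.078 with 1 library left out). Its median log2 fold change was 0.14 and its mean 0.40, and 26 of the 30 genes were not called. Hmga2 (3.52) and Hmga1 (2.69) lay far above that median, and the list was not tested without them. Nap1l1 and Set were called only without Control 3 among the 6 fits that left out 1 library (adjusted p of up to 0.19 otherwise). In the integrated stress and unfolded protein response list of 25 tested genes, the 1-carbon enzyme gene Mthfd2 (2.40 ± 0.566 to 9.43 ± 0.357 FPKM), the asparagine synthetase gene Asns (1.43) and the cystine transporter gene Slc7a11 (1.27) rose, Sdf2l1 (-0.74) fell, and the list was not called (4 and 1 adjusted over the list alone, 7 and 4 without Control 3, adjusted p = 0.17). Mthfd2 was called in all 6 fits that left out 1 library, Asns in 2, and Slc7a11 and Sdf2l1 only without Control 3 (adjusted p of up to 0.20 otherwise). No ribosomal protein gene (39 tested, adjusted p = 0.086), mitochondrially encoded gene (13 tested, adjusted p = 0.29) or sex-linked gene (5 tested, adjusted p = 0.29) was called by limma in the comparison of all 6 libraries. Without Control 3, 7 of the 39 ribosomal protein genes were called higher and 1 lower. In that fit 1 of 13 mitochondrially encoded and 2 of 5 sex-linked genes were called higher. Over all 13128 features, that fit called 3142 higher and 2759 lower, so the ribosomal and mitochondrial counts show no excess of calls. The ribosomal list had adjusted p = 0.64 with an estimated correlation. At the preset correlation it was called without Control 2 (adjusted p = 7.4e-04) and without DEK cOE 3 (adjusted p = 0.020), in a range of 7.4e-04 to 0.34 with 1 library left out. It was also called with quantile normalization (adjusted p = 0.0051), with no filter on low values (adjusted p = 0.019) and with the GC term added after seeing the data (adjusted p = 0.027). The most abundant members were Rplp0, at 560.1 ± 100.8 FPKM in Control and 616.8 ± 25.5 FPKM in DEK cOE, and Rplp1, at 774.5 ± 326 and 905.9 ± 114 FPKM. The transcript mt-Co1 held 15753 ± 9598 and 11194 ± 617 FPKM, with 26808 FPKM in Control 3, and mt-Cytb 5646 ± 807 and 6782 ± 658 FPKM. Xist was at 98.1 ± 17.9 and 108.8 ± 10.5 FPKM and Eif2s3y at 6.82 ± 0.509 and 7.87 ± 0.804 FPKM.

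Most markers of other cell types lay under the filter on low values. Of 25 microglia and macrophage markers, 2 were expressed enough to be tested: Cd68 rose from 3.04 ± 1.16 to 7.18 ± 0.544 FPKM, and the other 23 summed to 1.46 ± 0.965 FPKM in Control and 1.53 ± 0.524 FPKM in DEK cOE. Of 22 endothelial markers 3 were tested and Flt1 rose (1.17 ± 0.415 to 3.49 ± 0.593 FPKM). Of 27 mural, fibroblast and meningeal markers 5 were tested and Fn1 (6.35 ± 1.14 to 19.3 ± 3.43 FPKM), Col6a1 (0.97) and Acta2 (0.89) rose (3 and 1 adjusted over the list alone). The list was not called by camera (adjusted p = 0.13) but was called as higher by fry (adjusted p = 0.029). Of 27 ependymal markers 7 were tested. The cilium genes Meig1 (2.24 ± 0.774 to 0.102 ± 0.0996 FPKM), Dynlrb2 (-1.62) and Cfap44 (-1.03) fell, while Tm4sf1 (0.376 ± 0.141 to 3.85 ± 1.36 FPKM), which is also in the reactive-astrocyte list, rose. Adjusted over the list alone, 5 ependymal genes were lower and 1 higher, and 6 were lower and 1 higher without Control 3. The ependymal list had camera adjusted p = 0.013, and adjusted p = 0.22 with an estimated correlation. Enpp2, the 1 tested choroid plexus gene of 13, fell from 10.6 ± 2.70 to 2.02 ± 0.0218 FPKM, and 0 of 8 erythroid genes were expressed enough to be tested. The members under the filter were also summed per list, with no test. The sums in Control and DEK cOE were 7.75 ± 2.87 and 3.08 ± 0.357 FPKM for 20 ependymal markers and 6.37 ± 0.949 and 1.98 ± 0.13 FPKM for 15 of the oligodendrocyte lineage. They were 2.35 ± 0.583 and 3.22 ± 0.386 FPKM for 19 endothelial markers, 3.99 ± 0.102 and 4.52 ± 0.0457 FPKM for 22 mural, fibroblast and meningeal markers, and 4.68 ± 0.184 and 5.19 ± 0.174 FPKM for 15 neuroblast and neuron genes. For 12 choroid plexus markers they were 1.496 ± 0.405 and 1.346 ± 0.34 FPKM, and for 8 erythroid genes 1.91 ± 1.05 and 1.96 ± 0.721 FPKM. Fn1, Meig1, Tm4sf1 and Enpp2 were called in all 6 fits that left out 1 library, Col6a1 and Cfap44 in 5, Cd68, Acta2 and Dynlrb2 in 2, and Flt1 only without Control 3 (adjusted p of up to 0.071 otherwise).

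**Figure D3:**
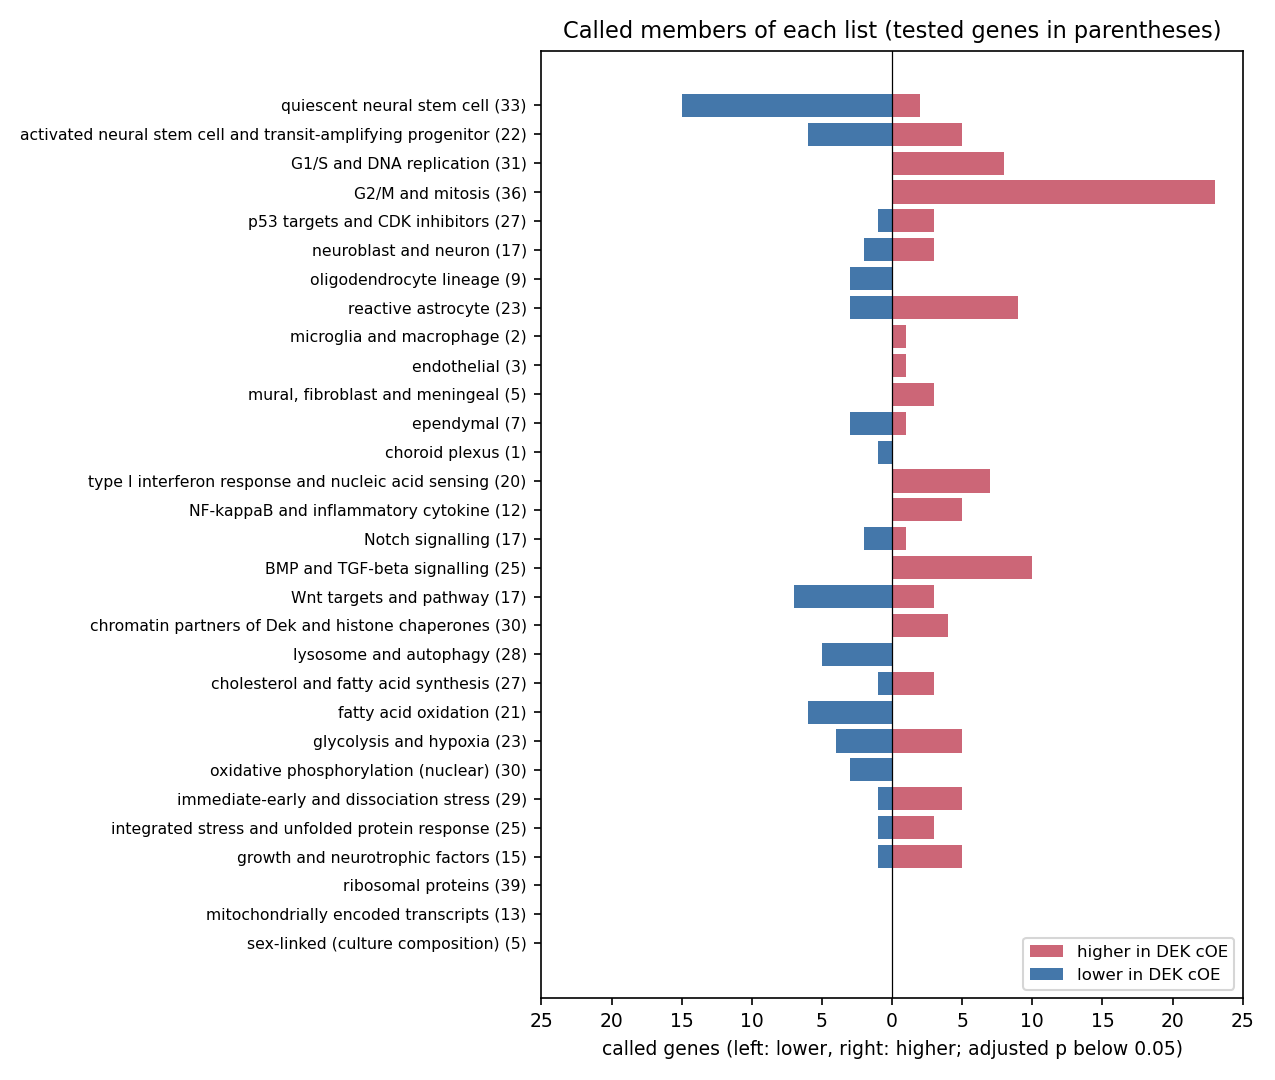
Number of called genes per list (adjusted p below 0.05), with genes higher in DEK cOE to the right and lower to the left of 0 and the number of tested genes in parentheses. The G2/M and mitosis list has 23 genes higher and 0 lower, and the quiescent neural stem cell list has 2 higher and 15 lower.

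Of the 113 called genes that the naming rule selects, 56 were called in all 6 fits that left out 1 library. Fold changes are on the log2(FPKM + 1) scale, which understates the change of genes near or below 1 FPKM.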

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

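The alternatives with GC trends, sample weights, voom and a GC term, and the one that combines the GC trend with the removal of Control 3, were chosen after seeing the data. Dek kept its direction and its call in 19 alternatives, with log2 fold changes between 4.02 and 4.41 and adjusted p-values between 4.1e-07 and 0.0088. The counts of 804 higher and 921 lower genes stayed within 1.5 times under a pseudocount of 0.1, the filter of 1 RPM, each of 4 scalings, voom and the GC term, and in each of these every call shared with the comparison of all 6 libraries kept its sign. They fell to 416 and 558 with no filter on low values, where more features were tested, to 201 and 315 at an adjusted p below 0.01, and to 309 and 461 with a log2 fold change of at least 1. They rose to 1679 and 1632 with the GC trend removed, to 4294 and 3761 with sample weights and to 2813 and 2396 with Control 3 left out and the GC trend removed, for which the cause was not tested. Leaving out 1 library gave between 148 and 3142 higher and between 246 and 2759 lower genes, the highest of each without Control 3 and the lowest without DEK cOE 3. With the replicate block there were 686 higher and 806 lower genes. The labels do not say what the numbers share, and the deviations of same-numbered libraries correlated at 0.351, -0.075 and 0.297, so the numbers were not taken as pairs; DEK cOE 2 correlated best with Control 3 (0.139) and not with its own number. Alternatives that need a table of counts were planned for such a table and not run.

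With an estimated correlation the adjusted p was 0.071 for the quiescence list, 0.16 for G1/S and 0.20 for G2/M, and 0 of the 15 called lists kept its call; in all other alternatives between 14 and 18 lists were called. Results that changed direction were called neither before nor after. They were Rplp1 (between -0.035 and 0.61 with 1 library left out) and mt-Co1 (between -0.61 and 0.13), both turned only without Control 3, mt-Co1 (0.085) with sample weights, Xist (-0.011) and Eif2s3y (-0.059) with the GC trend removed, and mt-Cytb (-0.24), Xist (-0.033) and Eif2s3y (-0.25) with Control 3 left out and the GC trend removed, all as log2 fold changes. The neuroblast and neuron list turned at adjusted p = 0.983 with a pseudocount of 0.1, 0.960 with library size only, 0.875 with the replicate block, and 0.986, 0.824 and 0.853 without Control 1, Control 2 and DEK cOE 1 (the range with 1 library left out was 0.824 to 0.986). It also turned at 0.998 with voom, 0.686 with the GC trend removed, 0.954 with sample weights, 0.871 with the GC term and 0.861 with Control 3 left out and the GC trend removed. The glycolysis list turned at 0.469 with no filter, 0.585 with the filter of 1 RPM, 0.764 with quantile normalization, and 0.824 without Control 2 and 0.829 without DEK cOE 3 (range with 1 library left out 0.730 to 0.986). It also turned at 0.931 with the GC trend removed, 0.903 with the GC term, 0.828 with Control 3 left out and the GC trend removed and 0.645 with fry. The Notch list turned at 0.875 with the GC term and 0.983 without Control 1 (range with 1 library left out 0.301 to 0.983). The mitochondrial list turned at 0.992 with the GC trend removed and 0.861 with Control 3 left out as well, and the sex-linked list at 0.861 with both. Their cause was not tested. Among single named genes, 290 results in the alternatives kept direction and lost the call and 1 gained it, and among lists 24 lost and 15 gained it. Lists that gained it in some alternative included p53 targets (lowest camera adjusted p = 0.046) and the integrated stress response (0.047). Mitochondrially encoded transcripts (0.047) and cholesterol and fatty acid synthesis (0.0040) also did. Of simulated 2-fold changes, 18% were called at the spread of all 6 libraries and 68% at the spread estimated without Control 3. Far fewer genes were changed in the simulation than were called in the data, so these shares can understate the sensitivity of the real comparison.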

Other observations

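Of the tests below, those of the correlations of Control 3, of its Dek level, of the GC trend, of the removal of Control 3, of the parts that share no library and of the summed gain of cytokine genes were chosen after the result was seen. The tests of macrophage markers, of the ERK and oligodendrocyte precursor genes and of other splits of the libraries were written before their results were seen.

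ERK signalling is the kinase pathway downstream of growth factor receptors. Its feedback phosphatase gene Dusp6, the EGF receptor ligand gene Hbegf and Spry4 had been seen to rise, so a further list of ERK feedback and target genes was written without them, from genes whose group difference had not been examined, except that the values of Egr4 had been displayed. Of 18 tested genes, 8 rose and 1 fell (12 and 2 without Control 3). Spry1 rose from 7.86 to 45.2 FPKM and Dusp4 from 6.41 to 32.8 FPKM, with Spred3, Areg and Epha2 also higher and Ets1 lower. Etv4 (29.3 and 30.8 FPKM in Control and DEK cOE) and Etv5 (78.9 and 77.8 FPKM) were not called. Camera gave adjusted p = 0.0011 over 2 such lists and adjusted p = 0.024 with an estimated correlation. The fixed lists were adjusted over 27 lists, so these values cannot be set against theirs. With an estimated correlation the quiescence list had an unadjusted camera p of 0.0026, which became an adjusted p of 0.071. Of 29 tested immediate-early genes, Dusp5 and Dusp6 among them, 5 rose and 1 fell. That fixed list was called by camera (adjusted p = 0.0042) but not by fry (adjusted p = 0.15). Camera did not call it with an estimated correlation (adjusted p = 0.56) or without Control 3 (adjusted p = 0.18). A candidate explanation is a higher output of ERK signalling in DEK cOE cells, with Egfr lower at the same time. It is a hypothesis from the same libraries, and neither ERK activity nor the cells' growth factor supply was measured here.

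Gjc3, Omg and Bcas1 had been seen to fall, and a list of other genes of oligodendrocyte precursors was written in the same way. Of 22 tested genes, 11 fell and 0 rose (13 and 0 without Control 3), with camera adjusted p = 3.1e-08 and adjusted p = 0.012 with an estimated correlation. Both were adjusted over the same 2 lists and cannot be set against the values of the fixed lists. Sox8 fell from 127 to 45.2 FPKM, Gpr37l1, which astrocytes also express, from 200 to 68.3 FPKM, Luzp2 from 6.87 to 1.81 FPKM and Cacng4 from 11.0 to 3.44 FPKM. Ptprz1 (314 and 190 FPKM) and Fyn (65.3 and 65.2 FPKM) were not called. In the fixed oligodendrocyte-lineage list, 3 of 9 tested genes fell and 6 were not called. Genes associated with quiescent neural stem cells, astrocyte genes among them, fell too (15 of 33 tested, with 2 higher). Whether the fall is particular to oligodendrocyte precursors was therefore not settled. If it is, these values may reflect lower expression of the programme per cell or fewer cells that carry it, and bulk values do not separate these. The genes named here and in the preceding paragraph were picked from their lists after their values were seen.

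The number of called genes was 1725 for DEK cOE against Control, and the highest of the other 9 splits of the 6 libraries into 3 and 3 was 0 by limma. These 10 splits, of which 1 reached the real value, are too few for a share under 0.05. The split of Control 1, Control 2 and DEK cOE 1 from the rest, which follows the GC trend, called 0 genes with 2677 at an unadjusted p below 0.05, against 3762 for the real split. DEK cOE 1 against Control 1 and 2, and DEK cOE 2 and 3 against Control 3, share no library. Their log2 differences correlated across genes, which are not independent replicates (Pearson's r = 0.458, Spearman's rho = 0.371), and Dek differed by 4.26 and 3.98.

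Control 3 differed from Control 1 and 2 more than other replicates differed from each other, and a GC-dependent bias as the whole cause is argued against by the mean correlation of Control 3 with Control 1 and 2 after the GC trend was removed. It rose from 0.887 to 0.940 over 12880 genes and stayed below the lowest of the other pairs within a group (0.977), so the trend may account for part of the difference. RNA of DEK cOE cultures as the whole cause is argued against by the level of Dek, which allows a share of such RNA in Control 3 of at most 2.38% (1.64% to 2.38% over pairs of libraries). At that share a computed mixture of Control 1 or 2 with a DEK cOE library correlated with the other at 0.985 or above over 13128 genes, against 0.884 for Control 3, while tests by displacement towards DEK cOE (median 18.2%, quartiles -3.41% and 51.5%, 412 genes) and by the correlation of Control 3 alone had decided nothing and were replaced. A different state of that culture stays open, and so do technical differences other than these 2. No biological explanation and no further technical one was tested, since the labels give no further property of the replicates.

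Of 12 tested NF-kappaB and cytokine genes 5 were called higher in DEK cOE, and of 20 tested interferon response genes 7. Macrophages or microglia in the DEK cOE cultures were tested by their other markers. The summed level of 23 markers was 1.04 times the Control sum, a gain of 0.0651 FPKM. The 12 called cytokine and interferon genes gained 47.2 FPKM together. The marker sums were 1.26, 2.51 and 0.615 FPKM in Control 1, 2 and 3. They were 0.926, 1.76 and 1.89 FPKM in DEK cOE 1, 2 and 3. At such low and scattered values the ratio does not decide, though these markers were scarce in both groups. A GC-dependent bias as the whole cause is argued against by the lists after the trend was removed, where the larger adjusted p was 0.0018 at the preset correlation; with an estimated one and no GC step, neither list was called (adjusted p = 0.29 and adjusted p = 0.31). Cd68, left out of the marker sum, rose, and the 23 summed markers lay under the filter on low values. A response of the infected cells to DEK or to the dose of vector stays open, since vector genomes per cell were not measured here.

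Of 33 tested quiescence-associated genes 15 fell and 2 rose, and of 36 tested genes of G2/M and mitosis 23 rose and 0 fell. Control 3 alone is argued against as the cause by the lists without it, where the larger adjusted p was 6.9e-06 (over all alternatives it lay between 9.0e-09 and 0.071 for quiescence and between 6.0e-21 and 0.20 for mitosis), and a GC-dependent bias as the whole cause by the lists with the trend removed, where it was 9.9e-08. These values use the preset correlation, and with an estimated one neither list was called with all 6 libraries (adjusted p = 0.071 and adjusted p = 0.20) or without Control 3 (adjusted p = 0.21 and adjusted p = 0.084). More cells in division, or more transcript per dividing cell, stay open, since cells were not counted here. The fall of Egfr and Dll1 beside the rises of mitotic genes may be of interest, as these genes are usually high in activated stem cells.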
